A study of Homo sapiens and Mus musculus with 19 samples.

How the data were processed

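The series holds 19 arrays of retrovirally transduced lung cancer cells, 15 from 5 human lines (A549, H23, H358, HCC827 and PC9, 3 vectors each) and 4 from mouse Lewis lung carcinoma cells (named LLC-kB OVA in the labels and LLC here, 2 vectors with 2 arrays each). Per the labels, total RNA was made into biotin-labelled cRNA and hybridised to single-colour Affymetrix arrays. The deposited values are intensity per probe set on a linear scale, per the submitters' processing notes computed with GCOS 1.4 and MAS5. All values were checked to be above 0, and the mean without the lowest and highest 2 percent of each array was 500, which is the scaling the authors applied. MAS5 signals near the background are noisy, and scaling to a common mean removes any difference in total RNA between samples. Detection calls and scanner images were not used here.

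The human table held 54675 probe sets, of which 41097 name 1 gene, 1801 name several and 11777 name none, and the mouse table held 45101, of which 34958 name 1 gene, 932 several and 9211 none. Tests used the probe sets that name 1 gene, 19775 human and 18194 mouse genes, with the brightest probe set over all arrays of that species standing for the gene. Signals were taken as log2 of the value plus 16. A gene was kept when it lay above the 40th percentile of its array in at least 5 human or 2 mouse arrays, which left 15212 human and 12549 mouse genes. No further normalisation between arrays was applied. Where a gene lay below that percentile on every array of the lower group, its fold is a lower bound, taken with the percentile of each array in place of the gene's value there, a choice made after the data were seen.

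Groups followed the vector named in the labels, with the human replicate numbers 1 to 5 standing for the 5 lines. The human fit took all 15 arrays with the cell line as a block, and 3 contrasts were tested, IKKb against MiG, IkB_SR against MiG and IKKb against IkB_SR. The LLC fit compared 2 arrays with 2 without a block, and the same fit with the replicate number as a block is printed beside it, because the Dap spike-in signal split the arrays by number. The deviations of same-numbered arrays had a correlation across genes of 0.53, a single value since 2 arrays per vector deviate in mirror image. The labels do not say what the numbers stand for, so they are not known to pair the arrays. Tests were those of limma 3.58.1 (lmFit, and eBayes with an intensity trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

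There were 21 gene lists. They covered NF-kB pathway and feedback targets, chemokines, cytokines and growth factors, MHC class I antigen presentation, interferon-stimulated genes, adhesion and immune surface receptors, anti-apoptotic genes, proteases and matrix remodelling, cell cycle, epithelial genes, mesenchymal genes, the unfolded protein and integrated stress response, hypoxia and glycolysis, cholesterol biosynthesis, p53 targets, NRF2 targets, immediate-early genes, ribosomal proteins, and markers of alveolar and airway epithelium, of leukocytes and of fibroblasts and endothelium. The last 3 stand for other cell types that a culture or a sort could hold. Each list was tested with camera at a preset correlation of 0.01 between genes, again with the correlation estimated from the arrays, and with fry. Adjustment was over the 21 lists of a comparison. With an estimated correlation 3 of the 12 lists that passed between IKKb and MiG kept an adjusted p below 0.05, 0 of 7 between IkB_SR and MiG, 3 of 11 between IKKb and IkB_SR, 0 of 10 in LLC without the block and 0 of 9 with it. Fry, which asks whether the genes of a list move on balance in one direction, passed 6 lists between IKKb and IkB_SR, including the NF-kB list at an adjusted p of 0.00207, and 0 in each of the other comparisons. Where counts of list members are given, they are over all genes or adjusted over the list alone, as stated beside them.

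Named genes followed a rule. For each comparison with MiG it took up to 8 genes per direction with the largest fold change among those past the threshold in the same direction in all lines or arrays, and 5 per direction for IKKb against IkB_SR. Where fewer passed, 4 per direction with the smallest p were named, as values. The rule added up to 4 members past the threshold from each list, and a fixed set of NF-kB genes, cytokines and immune genes whether or not they passed. Some items named by the rule are not reported here. The grouping, tests, filters, lists and rule were set before the data were examined, as were most of the alternatives.

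The alternatives were pseudocounts of 1 and 64, quantile normalisation, median centring, no filter, a filter at the 60th percentile, the mean of the probe sets of a gene, eBayes without a trend or with a robust prior, no block, a fit on the arrays of the compared vectors only, and leaving out each line or each mouse array. Added after the data were seen were the fits without the H358 IKKb array, the LLC block combined with other settings, the NF-kB list without NFKBIA, and the overlap between the genes of IKKb against IkB_SR and those of LLC with the block. The shift of the NF-kB list per line was tested by an exact sign-flip permutation over the 5 lines, which cannot go below p = 0.063.

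The fits were tested on simulated data with the residual spread as shrunk by eBayes. In them 100 genes changed by log2 1 and 100 by log2 2, by the same amount in every line or array. Of those changed by log2 1, 77 were found for IKKb against MiG, 84 for IkB_SR against MiG and 81 for IKKb against IkB_SR. All 100 changed by log2 2 were found in each human contrast, and 8, 10 and 8 unchanged genes passed. Real responses differed between lines, which the simulation leaves out. CCL5, at log2 3.05 between IKKb and MiG, did not pass. In LLC without a block 0 of the genes changed by log2 1 and 44 of those changed by log2 2 were found, with 0 unchanged genes. With the block 77 and 99 were found, with 11 unchanged genes. The simulated LLC arrays kept the fitted differences between replicate numbers and took their spread from the blocked fit. The fit without a block was therefore bound to find fewer, so these counts do not show which fit suits the data. A simulated list of 20 genes moved by 0.5 was found in all 5 fits and 0 unmoved lists passed. The simulated genes were independent, so this does not test lists whose genes move together. In the human fit the NF-kB list had an estimated correlation of 0.263.

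Human and mouse genes were paired by symbol, since the arrays differ and signals cannot be compared across them. Probe sets naming several genes or none were left out of the main tests, because their signal cannot be given to 1 gene. No genome coordinates were used here.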

Results

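Gene expression was measured on 19 single-colour Affymetrix arrays, 15 with human and 4 with mouse probe sets. The human arrays covered 5 non-small cell lung cancer lines, A549, H23, H358, HCC827 and PC9, each carrying 1 of 3 retroviral vectors, with 1 array per line and vector. The mouse arrays covered Lewis lung carcinoma cells, named LLC-kB OVA in the labels and LLC here, with 2 of these vectors and 2 arrays per vector. The labels do not explain the term kB OVA, which all 4 mouse arrays share. MiG was the empty vector with a green fluorescent protein marker. The vector named IKKb carried an activated form of the kinase IKKβ, which releases NF-kB from its inhibitor, and the vector named IkB_SR carried a super-repressor form of that inhibitor, IkBα. Transduced cells were sorted on the fluorescent marker. The values are MAS5 signals, which the authors scaled to a trimmed mean of 500 on every array. Median signals ran from 51.3 to 76.5 on the human arrays and from 55.0 to 64.4 on the mouse arrays, and the number of arrays limits the precision. In the human lines p-values weigh a change against the differences in response between the lines. For LLC the labels do not say whether the replicates were separate cultures, so p-values there measure the spread between these samples. In both fits limma also draws on the spread of other genes. Log2 fold changes are of signals plus 16 and are given with the standard error of the limma fit. Where a gene lay below the 40th percentile of every array of the lower group, the fold is given as at least the ratio to that percentile.

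The transcripts of the transduced genes were examined first, as a check on the labels. The brighter of the NFKBIA probe sets, which read the gene of IkBα, was higher with IkB_SR than with MiG in 4 of the 5 human lines, by 1.60-fold in A549, 4.07-fold in H358, 7.08-fold in HCC827 and 6.05-fold in PC9. In the array labelled H23 IkB_SR the ratio was 0.782. NFKBIA is also a target of NF-kB, and this probe set stood at 3.91-fold and 3.34-fold over MiG with IKKb in H358 and HCC827, against 1.07-fold to 1.17-fold in the other 3 lines. For IKBKB, the gene of IKKβ, 1 dim probe set had a higher signal with IKKb than with MiG in all 5 lines, from 291.5 against 204.2 in A549 to 79.91 against 26.87 in PC9, but its MiG signals in HCC827 and PC9 lay below the 40th percentile of their arrays. The other 2 IKBKB probe sets did not follow the vector. One of them lay at 1.09 of MiG in A549, 1.35 in H23, 0.689 in H358, 0.891 in HCC827 and 0.774 in PC9, and the brightest, which represents the gene in the tests, had a log2 fold change of -0.19 ± 0.12 between IKKb and MiG (adjusted p = 0.911). In LLC, the brightest Nfkbia probe set was 2.19-fold and 2.09-fold higher with IKKb in the arrays numbered 1 and 2, and the brightest Ikbkb probe set 1.26-fold and 1.14-fold higher. The other Ikbkb probe sets differed in direction, at 1.2 and 0.935, 1.07 and 0.691, 0.511 and 0.484, and 2.01 and 2.11 of MiG. The labels do not say which of these probe sets lie within the transduced sequences, and single arrays per line allow no test within a line.

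**Figure D1:**
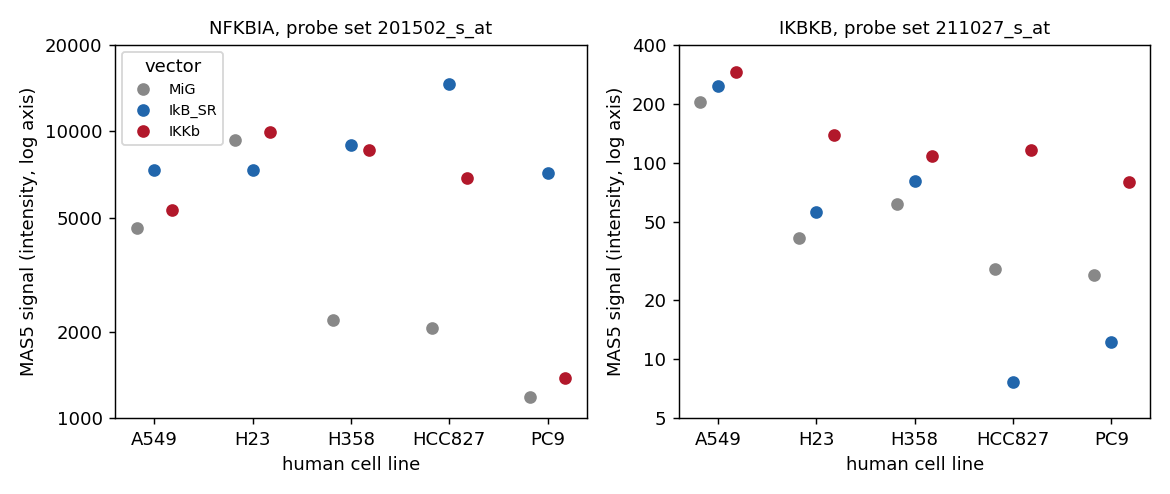
MAS5 signal (intensity, log axis) of the brighter NFKBIA probe set (left) and of 1 dim IKBKB probe set (right) in the 5 human lines, 1 point per array, coloured by vector. NFKBIA is higher with IkB_SR than with MiG in 4 lines and at 0.782 of MiG in H23, and IKBKB is highest with IKKb in all 5 lines.

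Activation of NF-kB was compared directly with its inhibition across the 5 human lines. The fold changes of this contrast use no control array, while its p-values draw on the spread of all 15 arrays. Genes of the NF-kB pathway and its feedback loop were higher with IKKb than with IkB_SR. RELB, an NF-kB subunit of the non-canonical pathway, was 4.47-fold higher (log2 2.16 ± 0.23, adjusted p = 0.000790, higher in 5 of 5 lines), and NFKB2, which encodes the precursor of its partner subunit, was 3.25-fold higher (log2 1.70 ± 0.21, adjusted p = 0.00160, 5 of 5 lines). TNFAIP3, a deubiquitinase that restrains NF-kB signalling, was 10.5-fold higher (log2 3.39 ± 0.41, adjusted p = 0.00143, 5 of 5 lines). The cytokine IL32 was at least 9.67-fold higher (adjusted p = 0.000790, 5 of 5 lines), with its IkB_SR signals below the 40th percentile on all 5 arrays. Of the 18 measured members of the list of NF-kB pathway and feedback targets, 11 rose and 0 fell over all genes tested, and 12 rose when adjusted over the list alone. The signalling adaptor TRAF1 rose with them by 3.25-fold, and the receptor TNFRSF9 by log2 1.82 ± 0.31, with 3 of its 5 IkB_SR signals below the 40th percentile. The list mean was 1.03 on the log2 scale (camera adjusted p = 1.95e-19, adjusted p = 0.0264 with an estimated correlation). NFKBIA, whose transcript the IkB_SR vector itself encodes, is 1 of the 18 members and did not pass the threshold (log2 -0.70 ± 0.39, adjusted p = 0.438).

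Transcripts of some chemokines, cytokines and surface receptors were higher as well. Of 15 measured chemokines, 5 rose over all genes tested and 8 did when adjusted over the list alone. CCL2, a monocyte attractant, was 10.95-fold higher (log2 3.45 ± 0.71, adjusted p = 0.0383) and CCL5 was higher by log2 3.21 ± 0.70 (adjusted p = 0.0458), with 3 of its 5 IkB_SR signals below the 40th percentile. The neutrophil attractants CXCL1 and CXCL2 were 4.54-fold and 4.41-fold higher (adjusted p = 0.0451 and 0.0239), and these 4 chemokines were higher in 5 of 5 lines. When 1 line was left out, CCL2 ran from log2 2.74 (without HCC827) to 4.29 (without PC9), CCL5 from 2.50 (without H358) to 3.84 (without A549) and CXCL1 from 1.48 (without HCC827) to 2.67 (without H23). CXCL8 and CCL20 had similarly large fold changes (log2 2.91 ± 0.74 and 3.29 ± 0.84) without passing the threshold (adjusted p = 0.0908 and 0.0910), as did IL6 (log2 2.09 ± 0.47, adjusted p = 0.0532), while CXCL10 lay at log2 1.18 ± 0.52 (adjusted p = 0.332). With 1 line left out, CXCL8 ran from log2 1.90 (without HCC827) to 3.65 (without H23). CCL20 then ran from 2.20 (without H358) to 4.07 (without A549) and IL6 from 1.32 (without HCC827) to 2.44 (without H358). Of the 5 IkB_SR signals, 4 lay below the 40th percentile for CCL20, 2 for IL6 and 1 for CXCL8. The chemokine list had a mean of 1.56 (camera adjusted p = 2.66e-10, adjusted p = 0.114 with an estimated correlation). Among 19 cytokines and growth factors, IL32 and the lymphotoxin gene LTB rose over all genes tested, LTB by 9.98-fold (log2 3.32 ± 0.67, adjusted p = 0.0351, 4 of 5 lines, log2 2.68 without HCC827 and 4.17 without H23), and 8 rose and 1 fell when adjusted over the list alone. That list had a mean of 0.98 (camera adjusted p = 4.22e-08, adjusted p = 0.0749 with an estimated correlation). Of 18 adhesion and immune surface receptors, 3 rose over all genes tested and 8 when adjusted over the list alone, with a list mean of 0.63 (camera adjusted p = 9.79e-11, adjusted p = 0.0264 with an estimated correlation). ICAM1, a ligand for leukocyte integrins, was 4.78-fold higher (log2 2.26 ± 0.28, adjusted p = 0.00207, 5 of 5 lines), with HCC827 at log2 3.72 and the other lines between 1.64 and 2.15. IL7R and CD47 rose by 2.77-fold and 1.61-fold, and CD274, which encodes the checkpoint ligand PD-L1, lay at log2 0.44 ± 0.16 (adjusted p = 0.253).

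**Figure D2:**
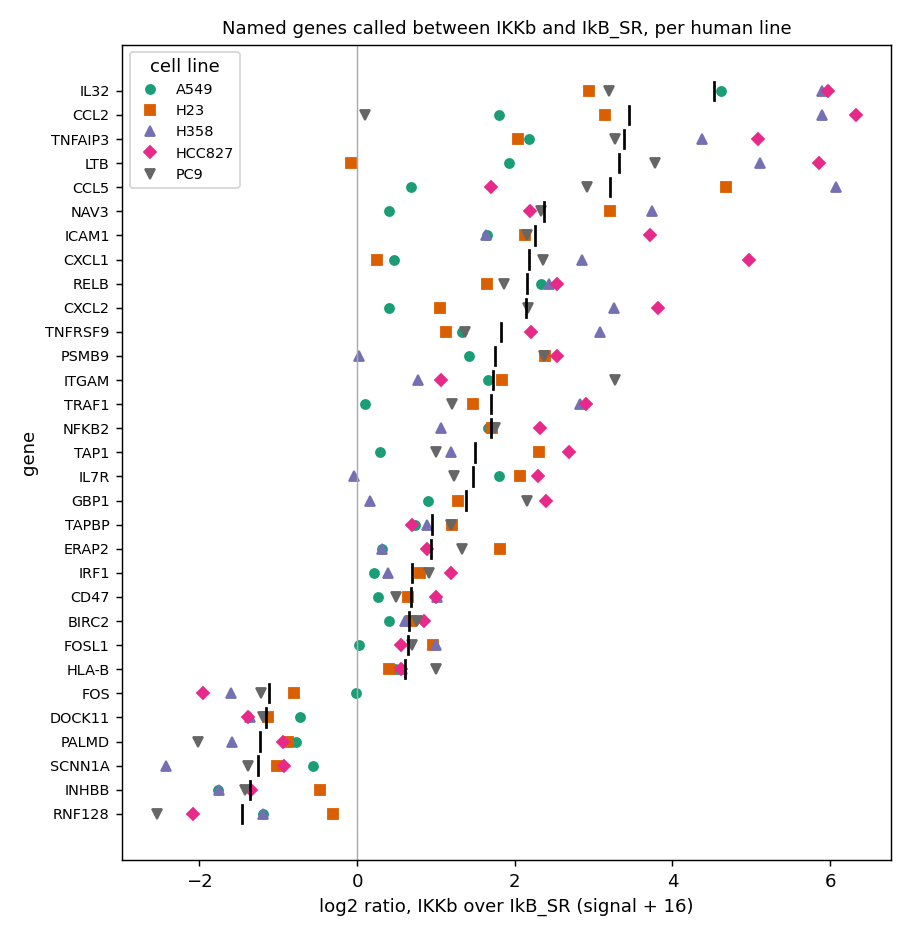
Log2 ratio of IKKb over IkB_SR (horizontal axis, signals plus 16) for the 31 named genes past the threshold (vertical axis), 1 point per human line, with the mean over the 5 lines as a vertical bar. RELB lies at 1.65 to 2.54 across the lines, and DOCK11 lies below 0 in all 5 lines. The IkB_SR signals of IL32 lie below the 40th percentile on all 5 arrays, so its points depend on the added 16.

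Genes that load peptides on MHC class I molecules were higher with IKKb than with IkB_SR. PSMB9, an immunoproteasome subunit, rose 3.35-fold (log2 1.74 ± 0.29, adjusted p = 0.0132), the peptide transporter TAP1 rose 2.82-fold (adjusted p = 0.0277), and the loading factor TAPBP rose 1.92-fold (log2 0.94 ± 0.12, adjusted p = 0.00211), each in 5 of 5 lines. The trimming peptidase ERAP2 rose 1.91-fold and HLA-B rose 1.52-fold (log2 0.60 ± 0.12, adjusted p = 0.0337), the latter with PC9 at log2 1.01 and the other lines between 0.41 and 0.57. The HLA-B probe set is of a type that can also bind transcripts of related genes. Of 18 measured members of this list, 8 rose over all genes tested and 15 did when adjusted over the list alone, with a list mean of 0.64 (camera adjusted p = 6.63e-18, adjusted p = 0.0425 with an estimated correlation). Of 26 interferon-stimulated genes, the GTPase GBP1 and the transcription factor IRF1 rose over all genes tested, by 2.60-fold and 1.63-fold, and 5 rose when adjusted over the list alone. The interferon list had a mean of 0.77 (camera adjusted p = 4e-10, adjusted p = 0.306 with an estimated correlation), and its mean was 3.11 in HCC827 against -0.39 to 0.42 in the other 4 lines.

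**Figure D3:**
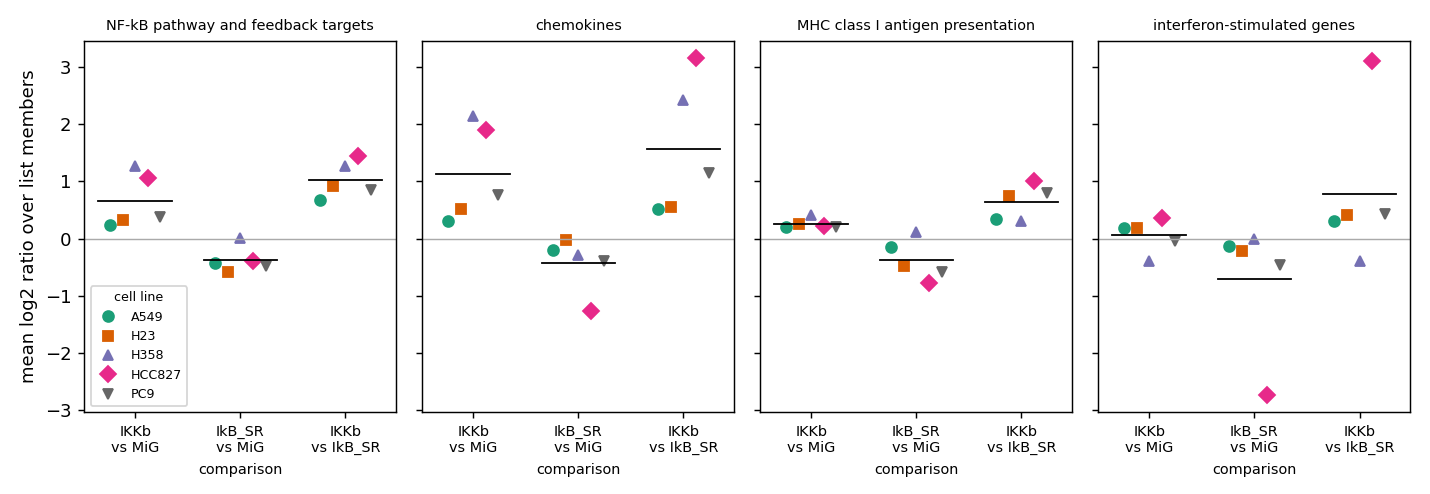
Mean log2 ratio over the members of 4 gene lists (vertical axis) in 3 comparisons (horizontal axis), 1 symbol per human line, with the mean over the 5 lines as a horizontal bar. The NF-kB list lies above 0 in all 5 lines for IKKb against MiG and for IKKb against IkB_SR, and the interferon list lies at -2.75 in HCC827 for IkB_SR against MiG.

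Among the genes lower with IKKb than with IkB_SR, RNF128, a ubiquitin ligase, was 2.75-fold lower (log2 -1.46 ± 0.27, adjusted p = 0.0250), INHBB, an activin subunit, 2.56-fold lower (log2 -1.35 ± 0.19, adjusted p = 0.00474), and SCNN1A, a subunit of the epithelial sodium channel, 2.40-fold lower (log2 -1.26 ± 0.24, adjusted p = 0.0298). PALMD and DOCK11, a guanine nucleotide exchange factor, were 2.36-fold and 2.23-fold lower (adjusted p = 0.0136 and 0.000790), and these 5 genes were lower in 5 of 5 lines. NAV3 was 5.19-fold higher (log2 2.38 ± 0.36, adjusted p = 0.00735). Of 20 immediate-early genes, the AP-1 subunit FOS fell 2.17-fold (adjusted p = 0.0402) and its relative FOSL1 rose 1.57-fold (adjusted p = 0.0369), and 3 rose and 1 fell when adjusted over the list alone. That list had a mean of 0.09 (camera adjusted p = 0.0444, adjusted p = 0.124 with an estimated correlation). Of 11 anti-apoptotic genes, the apoptosis inhibitor BIRC2 rose 1.58-fold (adjusted p = 0.00682) and 2 rose when adjusted over the list alone, with a list mean of 0.32 (camera adjusted p = 0.0191, adjusted p = 0.124 with an estimated correlation).

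The remaining lists moved less or without members past the threshold. Proteases and matrix remodelling genes had a mean of 0.32 with 0 of 16 members past limma's threshold over all genes and 4 higher when adjusted over the list alone (camera adjusted p = 0.0408, adjusted p = 0.132 with an estimated correlation). Hypoxia and glycolysis genes lay at -0.18 (camera adjusted p = 0.00634, adjusted p = 0.132 with an estimated correlation) and cholesterol biosynthesis genes at -0.22 (camera adjusted p = 0.00394, adjusted p = 0.472 with an estimated correlation). Without the H358 IKKb array the cholesterol list lay at -0.08 (camera adjusted p = 0.308), while the stress response list named next lay at 0.13 (0.0409) and ribosomal proteins at -0.11 (0.0413). Cell cycle genes (mean 0.05, camera adjusted p = 0.349), epithelial genes (-0.04, 0.601), mesenchymal genes (0.14, 0.149), unfolded protein and integrated stress response genes (0.10, 0.166), p53 targets (-0.15, 0.278), NRF2 targets (-0.09, 0.224), alveolar and airway markers (-0.13, 0.766), fibroblast and endothelial markers (-0.07, 0.766) and ribosomal proteins (0.01, 0.766) did not pass the list test. Of 11 leukocyte markers, the myeloid integrin ITGAM rose by log2 1.72 ± 0.34 in 5 of 5 lines (adjusted p = 0.0327), with 3 of its 5 IkB_SR signals below the 40th percentile. Adjusted over the list alone 1 leukocyte marker rose and 1 fell, and the list as a whole did not pass its test (camera adjusted p = 0.998). Several of these lists lay apart in H358, where cell cycle genes lay at 0.53, epithelial genes at -0.64 and alveolar and airway markers at -0.83, outside the range of the other 4 lines. The H358 IKKb array also stood apart in its spike-in signal (4376 for Dap, against 1128 and 1103 on the other H358 arrays) and in its 3' to 5' signal ratio of actin (1.74, against 1.41 and 1.38).

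In this contrast limma found 142 of 15212 genes past an adjusted p of 0.05, 93 higher and 49 lower with IKKb, of which 40 and 8 differed by at least 2-fold, and 136 had the same direction in all 5 lines. The count was 67 without H23, 31 without HCC827 and 24 without PC9, and 97 without the H358 IKKb array, of which 82 were among the 142. It was 15 with the arrays of the compared vectors only, 21 without an intensity trend, 45 with the mean of the probe sets of a gene and 86 with no filter on dim genes. Of the 31 named genes past the threshold, 16 lay below the 40th percentile on 1 to 3 of the 5 arrays of the lower vector, so their folds depend on the added 16. With pseudocounts of 64 and 1 the fold of CCL5 was 5.41 and 14.8, that of CCL2 7.74 and 17.7 and that of LTB 6.16 and 14.1. With the cell line left out of the model as a block, 0 genes passed in limma and 87 had an unadjusted p below 0.05, where chance alone gives 761.

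Activated IKKb was also compared with the empty vector, which asks what added NF-kB activity does to these lines. Here the list of NF-kB targets rose, with a mean above 0 in each of the 5 lines, while no single gene passed the threshold. IL32 had a log2 fold change of 2.76 ± 0.48 (adjusted p = 0.404), TNFAIP3 of 1.80 ± 0.41 (adjusted p = 0.801), RELB of 1.08 ± 0.23 (adjusted p = 0.619) and CCL5 of 3.05 ± 0.70 (adjusted p = 0.829), each above 0 in 5 of 5 lines. IRAK2, a kinase of interleukin-1 and Toll-like receptor signalling, had the smallest adjusted p of all genes (log2 0.99 ± 0.16, adjusted p = 0.354, 5 of 5 lines), followed among the genes above 0 by IL32, the NF-kB inhibitor NFKBIE (log2 0.96 ± 0.19) and the TNFAIP3 partner TNIP1 (log2 0.73 ± 0.15), the latter pair at an adjusted p of 0.590. On the negative side lay DOCK11 (log2 -0.66 ± 0.13), EMILIN3 (-1.21 ± 0.26), PTPRS (-0.68 ± 0.15) and LTBP3, which binds latent TGF-beta (-0.44, with A549 at -0.27 and the other lines between -0.53 and -0.46), at adjusted p from 0.590 to 0.619. ICAM1 lay at log2 1.31 ± 0.28, CCL2 at 2.10 ± 0.71, CCL20 at 2.28 ± 0.84, CXCL8 at 1.77 ± 0.74, CXCL1 at 1.19 ± 0.47, CXCL10 at 1.33 ± 0.52, NFKBIA at 0.84 ± 0.39, NFKB2 at 0.73 ± 0.21 and HLA-B at 0.27 ± 0.12, none past the threshold. CD274 lay at 0.16 ± 0.16. IL6 lay at 1.04 ± 0.47, with HCC827 at 2.93 and the other lines between 0.36 and 0.96. Of the 5 MiG signals, 3 lay below the 40th percentile for each of IL32, CCL5, CCL20 and CXCL10, and 2 for CCL2. For EMILIN3 this held for 4 of the 5 IKKb signals.

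As a group, the 18 NF-kB targets rose with IKKb by a mean of 0.66 on the log2 scale (camera adjusted p = 1.77e-18, adjusted p = 0.0473 with an estimated correlation), and 12 of them rose when adjusted over the list alone. Per line the mean was 0.24 in A549, 0.33 in H23, 1.27 in H358, 1.07 in HCC827 and 0.37 in PC9. An exact two-sided sign-flip permutation test over the 5 lines gave p = 0.063, the smallest value that 5 lines allow. Without the H358 IKKb array the mean was 0.55 (camera adjusted p = 4.01e-17). Chemokines lay at 1.13 (camera adjusted p = 1.17e-10, adjusted p = 0.0994 with an estimated correlation), with 10 of 15 higher when adjusted over the list alone. Cytokines and growth factors lay at 0.66 (camera adjusted p = 5.76e-08, adjusted p = 0.0763 with an estimated correlation, 4 of 19 higher adjusted over the list alone), and MHC class I presentation genes at 0.26 (camera adjusted p = 2.34e-09, adjusted p = 0.109 with an estimated correlation, 1 of 18). Adhesion and immune surface receptors (0.36, camera adjusted p = 5.23e-08, 2 of 18 higher adjusted over the list alone) and proteases and matrix remodelling genes (0.28, camera adjusted p = 0.000552, 2 of 16) each kept an adjusted p of 0.0473 with an estimated correlation. Interferon-stimulated genes lay at 0.06 (camera adjusted p = 0.183), at -0.40 in H358, and at 0.26 without the H358 IKKb array (camera adjusted p = 0.000179).

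Smaller list shifts between IKKb and MiG passed the preset correlation and not the estimated one. These were the unfolded protein and integrated stress response (0.17, camera adjusted p = 0.00036), NRF2 targets (0.10, 0.00924), immediate-early genes (0.06, 0.0466), ribosomal proteins (0.08, 0.0378), hypoxia and glycolysis genes (-0.10, 0.0466) and cholesterol biosynthesis genes (-0.23, 8.32e-05). With an estimated correlation their adjusted p was 0.132 for immediate-early genes, 0.637 for ribosomal proteins and 0.251 for the other 4 lists. Without the H358 IKKb array, ribosomal proteins lay at -0.04 (camera adjusted p = 0.631) and cholesterol genes at -0.08 (camera adjusted p = 0.162), while cell cycle genes lay at -0.10 (camera adjusted p = 0.000843, against -0.01 and 0.664 with it) and anti-apoptotic genes at 0.18 (0.0126, against 0.17 and 0.0677). The mean of the cholesterol list was -0.77 in H358 and between -0.23 and 0.05 in the other lines. Over all genes, limma found 0 of 15212 past an adjusted p of 0.05 between IKKb and MiG, with 839 at an unadjusted p below 0.05, where chance alone gives 761.

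The super-repressor was compared with the empty vector to ask what the lines lose when NF-kB is held back. No single gene passed the threshold, and the mean of the NF-kB list lay below 0 in 4 of the 5 lines. RELB had a log2 fold change of -1.09 ± 0.23 (adjusted p = 0.726) and TNFAIP3 of -1.59 ± 0.41 (adjusted p = 0.865), each below 0 in 5 of 5 lines. NFKB2 lay at -0.97 ± 0.21 (adjusted p = 0.726), with H358 at 0.30 and the other lines between -1.40 and -1.17. ICAM1 lay at -0.95 ± 0.28 (adjusted p = 0.995), with H358 at 0.19 and the other lines between -1.40 and -1.03. TAP2, a subunit of the peptide transporter, had the smallest adjusted p of all genes (log2 -0.61 ± 0.10, adjusted p = 0.563, below 0 in 5 of 5 lines). It was followed below 0 by RELB, the uncharacterised LOC100996740 (-0.76 ± 0.14) and MYBL1 (-0.63 ± 0.13), each at an adjusted p of 0.726. Above 0 lay INHBB (log2 0.99 ± 0.19, adjusted p = 0.726), CD6 (1.05 ± 0.24), FBLN1 (0.66 ± 0.16) and TGM5 (at least 1.5-fold), the last 3 at an adjusted p of 0.824. The MiG signals of TGM5 lay below the 40th percentile on all 5 arrays, and those of CD6 on 3 of 5. NFKBIA itself lay at 1.55 ± 0.39 (adjusted p = 0.824, 4 of 5 lines). CCL2 lay at -1.36 ± 0.71, CXCL8 at -1.14 ± 0.74, IL6 at -1.06 ± 0.47, CCL20 at -1.01 ± 0.84, CXCL1 at -0.99 ± 0.47, HLA-B at -0.33 ± 0.12, CD274 at -0.28 ± 0.16, CCL5 at -0.16 ± 0.70 and CXCL10 at 0.15 ± 0.52, none past the threshold. Of the 5 IkB_SR signals, 4 lay below the 40th percentile for CCL20, 3 for CCL5, and 2 each for CCL2 and IL6. For CXCL10 this held for 3 of the 5 MiG signals.

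The NF-kB list fell by 0.38 on the log2 scale with IkB_SR (camera adjusted p = 3.43e-09, adjusted p = 0.115 with an estimated correlation), and 6 of 18 members were lower and 1 higher when adjusted over the list alone. Per line it lay at -0.43 in A549, -0.59 in H23 (where NFKBIA stood at 0.782 of MiG), -0.38 in HCC827 and -0.47 in PC9, and at 0.00 in H358, where NFKBIA stood at 4.07-fold over MiG. The list counts NFKBIA, which the vector encodes, and without it the mean was -0.49 (camera adjusted p = 5.13e-12, adjusted p = 0.1 with an estimated correlation) and -0.11 in H358, where 9 of 17 members lay below 0. With NFKBIA counted, the exact two-sided sign-flip permutation test over the 5 lines gave p = 0.125, and without it 0.063, the smallest possible value. MHC class I presentation genes fell by 0.38 (camera adjusted p = 5.04e-13, adjusted p = 0.115 with an estimated correlation), with 9 of 18 lower when adjusted over the list alone, and lay at 0.12 in H358 and between -0.79 and -0.14 in the other lines. Interferon-stimulated genes fell by 0.71 (camera adjusted p = 5.04e-13, adjusted p = 0.336 with an estimated correlation), with HCC827 at -2.75 and the other lines between -0.46 and -0.01. Chemokines (-0.44, camera adjusted p = 0.0209, adjusted p = 0.678 with an estimated correlation), cytokines and growth factors (-0.33, 0.0209, and 0.535) and adhesion and immune surface receptors (-0.27, 8.9e-05, and 0.115) had means below 0 in all 5 lines. They passed at the preset correlation only. The chemokine mean was -1.26 in HCC827 and between -0.40 and -0.03 in the other lines. NRF2 targets, genes of the oxidative stress response, rose by 0.18 (camera adjusted p = 2.54e-06, adjusted p = 0.115 with an estimated correlation). Cell cycle genes lay at -0.06 without the H358 IKKb array (camera adjusted p = 0.0301, against 0.0961 with it). Over all genes, limma found 0 of 15212 past an adjusted p of 0.05, with 675 at an unadjusted p below 0.05, where chance alone gives 761. Without the 3 H358 arrays 8 genes passed, 2 higher and 6 lower. Named after their values were seen, the 6 lower were RELB, NFKB2, PSMB9, TAPBP, NT5E and LOC100996740, and the 2 higher were INHBB and RHOB. PSMB9 lay at log2 -1.65 (adjusted p = 0.00396) and NFKB2 at -1.29 (adjusted p = 0.00239) in that fit.

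Whether the vectors drive opposite responses was examined over the genes as a whole, and on the NF-kB list. Of the 18 NF-kB targets, 13 lay above 0 with IKKb and below 0 with IkB_SR, RELB and TNFAIP3 among them. Over all genes 47.2 percent had opposite signs, in either direction, against 33.3 percent in simulations of unchanged groups with the same shared controls. Both comparisons share the 5 control arrays, which alone pushes the fold changes of a gene in the same direction. Across 15212 genes the log2 fold changes of IKKb and of IkB_SR against MiG had a correlation of 0.0463 and a covariance of 0.00211, against 0.499 and 0.0211 in simulations with unchanged groups and the same shared controls. With the control arrays split between the comparisons, the mean correlation over 20 splits was -0.115, from -0.163 to -0.0489, and the mean covariance was -0.00993. These correlations are across genes, which are not independent replicates. Limma found 0 genes past the threshold in both comparisons, since each alone had 0, with 839 and 675 at an unadjusted p below 0.05. Of the 142 genes that differed between IKKb and IkB_SR, all 93 higher and all 49 lower ones had IKKb and IkB_SR on opposite sides of MiG, in part because they were selected on that difference. The medians were 0.41 and -0.46 for the higher genes and -0.38 and 0.37 for the lower ones.

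In LLC cells, activated IKKb was compared with MiG to ask the same question in a mouse line. Mmp9, a gelatinase that degrades matrix, was at least 18.5-fold higher with IKKb (fitted fold 32 with 1 added to the signals and 10.8 with 64 added, which shrinks the folds of dim genes), the NF-kB inhibitor Nfkbie 11.6-fold higher (log2 3.54) and the acute-phase gene Saa3 12.3-fold higher (log2 3.62), each in the arrays numbered 1 and in those numbered 2. Saa3 lay at log2 2.98 without IKKb replicate 1 and at 4.25 without IKKb replicate 2. The chemokine Ccl2 was 5.37-fold higher (log2 2.42) and the NF-kB subunit Relb 3.61-fold higher (log2 1.85). Without a block none of these passed the threshold (adjusted p = 0.0552 for Mmp9 and Nfkbie, 0.276 for Saa3, 0.381 for Ccl2 and 0.915 for Relb). With the replicate number as a block their adjusted p was 5.46e-15 for Mmp9 and Ccl2, 5.32e-15 for Nfkbie, 2.97e-14 for Saa3 and 9.71e-08 for Relb. The 4 arrays leave the blocked fit almost no measure of a gene's own spread. These small values therefore rest mainly on the spread pooled over genes. The Dap spike-in split the arrays by replicate number, at 1679 and 1567 on the arrays numbered 1 and 28.7 and 19.4 on those numbered 2, while the BioB spike-in did not (486 and 157 against 272 and 280). The labels do not say what the numbers stand for, so the calls with the block rest on taking them as a processing difference. Without the block limma found 0 of 12549 genes past an adjusted p of 0.05, with 238 at an unadjusted p below 0.05, where chance alone gives 627. With it, 223 passed, 155 higher and 68 lower, of which 67 and 15 differed by at least 2-fold. The count with the block became 90 with quantile normalisation and 92 with no filter on dim genes. When 1 array was left out of the fit without a block, the count was 44 without MiG replicate 1, 138 without MiG replicate 2, 5 without IKKb replicate 1 and 10 without IKKb replicate 2. The 5 genes were Mmp9, Nfkbie, Saa3, Tmem176a and Tmem176b. In these 4 fits the lone array of a vector is assumed to vary like the other vector's arrays.

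**Figure D4:**
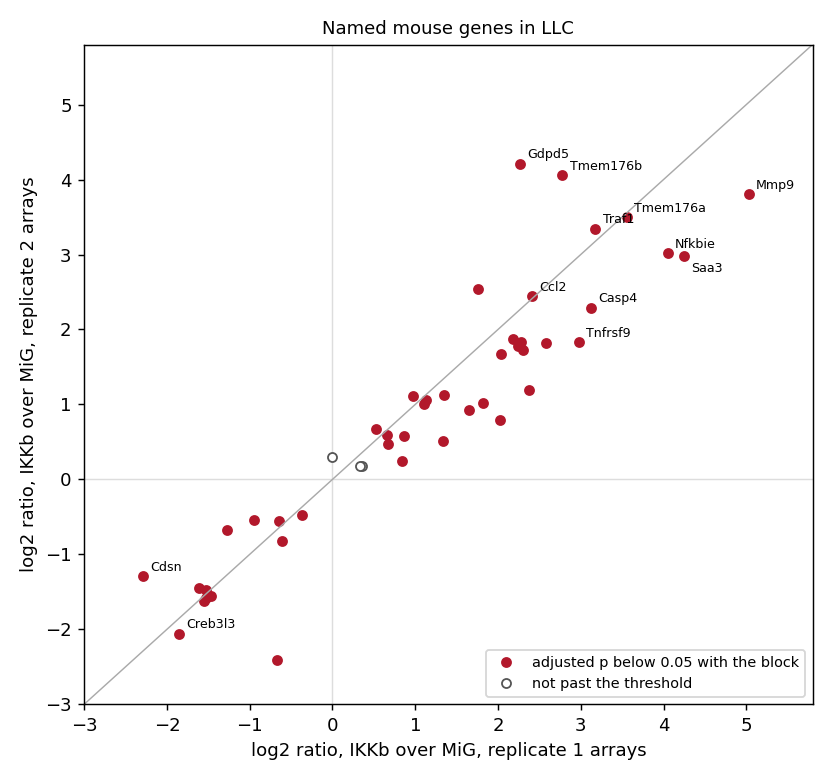
Log2 ratio of IKKb over MiG in LLC for the named mouse genes, in the arrays numbered 1 (horizontal axis) and in those numbered 2 (vertical axis), 1 point per gene, filled where the adjusted p lies below 0.05 with the replicate number as a block. Nfkbie lies at 4.05 and 3.02, and Ccl2 at 2.41 and 2.44. Points of genes dim with MiG, such as Mmp9, depend on the added 16.

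With the replicate block, 10 of 18 measured NF-kB targets rose in LLC over all genes tested and 15 did when adjusted over the list alone, against 0 and 9 without the block. Traf1 rose at least 4.85-fold, Tnfrsf9 5.29-fold (log2 2.40 ± 0.25) and the nuclear inhibitor family member Bcl3 by log2 2.15 ± 0.34, with 1 of its 2 MiG signals below the 40th percentile (log2 1.26 without MiG replicate 2 and 3.04 without MiG replicate 1), beside Tnfaip3 (2.65-fold), Nfkbia (2.14-fold) and Nfkb2 (1.65-fold). The NF-kB list mean was 1.25, with 1.45 in the arrays numbered 1 and 1.06 in those numbered 2 (camera adjusted p = 2.45e-36 with the block and 1.56e-28 without, adjusted p = 0.591 and 0.487 with an estimated correlation). In LLC the test with an estimated correlation had too few arrays for a list to pass readily, so it does not decide. Of 14 chemokines, 6 rose over all genes tested, and adjusted over the list alone 6 rose and 1 fell (6 and 0 without the block). Ccl7 rose 4.05-fold, Cxcl1 4.03-fold (2.46-fold without IKKb replicate 1 and 6.60-fold without IKKb replicate 2), Ccl5 at least 2.13-fold and Cxcl10 at least 1.77-fold, and the list mean was 0.69 (camera adjusted p = 1.25e-07 with the block and 0.000173 without, adjusted p = 0.591 and 0.487 with an estimated correlation). Of 13 proteases and matrix remodelling genes, Mmp9, Mmp13 (4.08-fold) and Mmp3 (2.35-fold) rose and the plasminogen activator Plat fell 1.68-fold, and adjusted over the list alone 4 rose and 1 fell (3 and 1 without the block). Their list mean was 0.65 (camera adjusted p = 0.000487 with the block and 0.00077 without, adjusted p = 0.591 and 0.487 with an estimated correlation).

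Other mouse genes passed the threshold with the block as well. The related membrane protein genes Tmem176a and Tmem176b rose 11.5-fold and 10.7-fold, the phosphodiesterase Gdpd5 by log2 3.24 ± 0.28 with 1 of its 2 MiG signals below the 40th percentile, and the inflammatory caspase Casp4 at least 2.42-fold. Lower with IKKb was Limch1 (2.90-fold), and among genes near the background the transcription factor Creb3l3 (at least 1.98-fold), Cdsn (at least 2.18-fold), Wbp2nl (at least 2.22-fold), Olfm2 (at least 1.44-fold), the keratin Krt19 (at least 1.5-fold), Spaca4 (at least 1.84-fold) and Myo5c (log2 -1.54 ± 0.36, with 1 of its 2 IKKb signals below the 40th percentile). Fn1 and Acta2, which encode fibronectin and smooth muscle actin, fell 1.97-fold and 1.52-fold, and of 15 mesenchymal genes these 2 passed over all genes and 4 were lower when adjusted over the list alone, against 0 and 0 without the block. The mesenchymal list fell by 0.27 (camera adjusted p = 0.000648 with the block and 0.000765 without, adjusted p = 0.591 and 0.487 with an estimated correlation), at -0.43 in the arrays numbered 1 and -0.11 in those numbered 2. Of 15 MHC class I presentation genes, Tapbp and Erap1 rose 2.06-fold and 1.54-fold, and H2-D1 lay at log2 0.15 ± 0.19 (adjusted p = 0.890). Of 17 adhesion and immune surface receptors, Il15ra and Ifngr2 rose 1.89-fold and 1.46-fold and Fas at least 1.91-fold, while Cd274 lay at 0.27 ± 0.32 (adjusted p = 0.884). Their list means were 0.17 (camera adjusted p = 0.0344 with the block and 0.0445 without) and 0.23 (0.0434 and 0.0252), and with an estimated correlation both had an adjusted p of 0.591 with the block. With 1 array left out, the MHC class I list ran from -0.09 to 0.43, so its direction is not settled, and the receptor list from 0.10 to 0.36. Adjusted over the list alone, 3 MHC class I genes and 4 receptors rose with the block, against 0 and 0 without it. Members of other lists also passed, among them Tgfb1, Tnfaip8, Trp53inp1, Slpi, Pdgfra and Gbp2 (at least 1.73-fold) on the higher side and Adm and Egr3 on the lower, the others of these 8 with folds from 1.34 to 2.44. Without MiG replicate 1 and without MiG replicate 2, Tmem176b rose 18.4-fold and 6.21-fold and Gdpd5 by log2 4.16 and 2.33. Without IKKb replicate 1 and without IKKb replicate 2, Myo5c lay at log2 -2.49 and -0.59, and Acta2 at 0.07 and -1.27. Ikbkb, represented by its brightest probe set, lay at 0.26 ± 0.11 (adjusted p = 0.351).

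Among the other mouse lists, p53 targets rose by 0.19 (camera adjusted p = 0.00538 with the block and 0.00267 without, adjusted p = 0.591 and 0.488 with an estimated correlation). Ribosomal proteins lay at -0.40, with -0.82 in the arrays numbered 1 and 0.03 in those numbered 2 (camera adjusted p = 0.0434 with the block and 7.45e-05 without, adjusted p = 0.646 and 0.488 with an estimated correlation). The unfolded protein and integrated stress response lay at -0.13, with -0.30 in the arrays numbered 1 and 0.03 in those numbered 2 (camera adjusted p = 0.0434 with the block and 0.0714 without, adjusted p = 0.591 with the block and an estimated correlation). Without the block, cell cycle genes (-0.10, camera adjusted p = 0.0252) and epithelial genes (-0.25, 0.0445) passed as well, each with an adjusted p of 0.488 with an estimated correlation. They lay at -0.17 and -0.53 in the arrays numbered 1, and at -0.03 and 0.03 in those numbered 2. Besides Mmp9, Nfkbie and Saa3, the gene with the smallest p above 0 in the fit without a block was the collagen Col8a1 (log2 1.41 ± 0.17, adjusted p = 0.308). Below 0 these were Glt8d2, Scara5, Ptn and Dkk2 (log2 -0.98, -1.39, -1.20 and -0.81, adjusted p = 0.9997).

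The responses of LLC and of the human lines to IKKb were then set side by side over 9706 genes paired by symbol. Against MiG, the log2 fold changes had a correlation across genes of 0.119 (Spearman 0.0195), and limma gave 0 genes past the threshold in both species. Over all tested genes, 839 human and 238 mouse genes had an unadjusted p below 0.05, where chance alone gives 761 and 627. Chosen after the data were seen, the genes higher with IKKb than with IkB_SR in the human lines were compared with those higher in LLC with the replicate block. Of 66 and 131 such genes, 17 were shared, where 0.891 would be by chance (one-sided Fisher's exact test, p = 8.16e-18). They were CCL2, CCL5, CXCL1, RELB, NFKB2, NFKBIE, TNFAIP3, TNIP1, TRAF1, TNFRSF9, IKBKE, TAPBP, ERAP1, DRAM1, GPR176, KLF10 and NEURL3. Of 42 and 60 genes lower, 1 was shared, LTBP3 (one-sided Fisher's exact test, p = 0.23). Fisher's test takes genes as independent, while genes of 1 pathway can move together, and it does not measure the spread between samples. Without the block 0 mouse genes passed, so 0 were shared. Of the 66 human genes, 50 lay above 0 in LLC, with a median of 0.23, and of the 42 lower ones 26 lay below 0, with a median of -0.051. Over all genes compared, 52.3 percent lay above 0 in LLC.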

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

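All tests of explanations below were chosen after the result was seen, except the fit without LLC MiG replicate 1, the counts of genes and lists over 100 splits of the samples and the count of genes over the 16 splits that part every line.

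In 13 of 146 sets of 5 line values examined, 1 line lay apart from the other 4, where chance gives about 7. H358 was the line apart in 7 of them, HCC827 in 4, and A549 and PC9 in 1 each. Between IKKb and MiG, LTBP3 lay at log2 -0.27 in A549 (others -0.53 to -0.46), IL6 at 2.93 in HCC827 (others 0.36 to 0.96), MHC class I presentation genes at 0.42 in H358 (others 0.21 to 0.26) and epithelial genes at -0.44 in H358 (others -0.04 to 0.11). Between IkB_SR and MiG, NFKB2 lay at 0.30 in H358 (others -1.40 to -1.17), ICAM1 at 0.19 in H358 (others -1.40 to -1.03) and interferon-stimulated genes at -2.75 in HCC827 (others -0.46 to -0.01). Between IKKb and IkB_SR, ICAM1 lay at 3.72 in HCC827 (others 1.64 to 2.15), HLA-B at 1.01 in PC9 (others 0.41 to 0.57) and interferon-stimulated genes at 3.11 in HCC827 (others -0.39 to 0.42). In the same contrast H358 lay at 0.53 for cell cycle genes (others -0.16 to 0.00), at -0.64 for epithelial genes (others -0.02 to 0.18) and at -0.83 for alveolar and airway markers (others -0.04 to 0.13).

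Of 83 genes and lists compared between species, 1 moved in opposite directions in all human lines and in the LLC arrays of both replicate numbers. TAP2, a subunit of the peptide transporter, had a mean log2 ratio of IKKb over MiG of 0.31 in the human lines and -0.22 in LLC, and the difference was not tested. Among 6825 human probe sets that name no single gene, 9 were higher and 1 lower with IKKb than with IkB_SR. Among 4544 such mouse probe sets, 2 were higher with IKKb in LLC without a block, and 38 were higher and 26 lower with the replicate block.

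The interferon-stimulated genes of HCC827 stood at a mean log2 signal of 11.54 with MiG, 11.90 with IKKb and 8.79 with IkB_SR, and all 26 measured members were lower with IkB_SR, 24 of them by at least log2 1, as far as -5.39 for IFI27. An array of another cell line is argued against by its correlation of at least 0.971 with the other HCC827 arrays, where different lines reach 0.892 at most. A scaling difference is argued against by a median log2 ratio of 0.0157 over all genes of this pair. Inhibition of NF-kB that lowers these genes wherever their control level is high stays open. H358, the line with the next highest level (9.75), lay at -0.0072. Its NF-kB list without NFKBIA lay at -0.11 (SD over members 0.47), with 9 of 17 members below 0. The other lines lay at -0.65 to -0.50 for that list. TNFAIP3 lay at -1.04 in H358, so how far NF-kB was held back there stays unclear. A change in the culture that has nothing to do with the vector may also be behind it and cannot be told apart, because there was 1 HCC827 IkB_SR array.

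The H358 IKKb array differed from the other H358 arrays in spike-in signal and 3' to 5' ratio, and 1061 genes lay at least 2-fold from MiG on it, against 431 to 915 in the other lines. A labelling batch or RNA quality as the whole cause of its NF-kB shift of 1.27 cannot be told apart from a response of this line, because there was 1 H358 IKKb array. The same holds for its other shifts. Across the genes outside the NF-kB list, its log2 ratios correlated with the mean of the other lines at 0.133. The highest such value of the other lines was 0.114, so the measure does not separate this array.

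In LLC, limma found 223 genes with the replicate number as a block and 0 without it. Without it 238 had an unadjusted p below 0.05, where chance alone gives 627. A processing batch that follows the replicate number is consistent with the Dap spike-in signal, at 1679 and 1567 against 28.7 and 19.4 (lowest over highest 54.6), while the BioB spike-in did not follow the number (486 and 157 against 272 and 280). The bright MiG replicate 1 as the cause stays open. The fit without it and without a block found fewer genes than the fit without MiG replicate 2. Both fits take a gene's own spread from the IKKb arrays alone. An odd MiG array left as the only control could itself add calls, so the counts cannot decide. No biological explanation was tested, since the labels do not say what the numbers stand for.

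Other splits of the human arrays were set against the real one, 100 drawn for each comparison with the real one included. The model blocks on the cell line. The drawn splits that keep both arrays of some lines in 1 group part only 1 line (23 of the 99 others) or 3 lines (61). Their other lines enter the contrast only through the arrays of the remaining vector. The 16 splits that part every line are therefore the ones like the real split. These 16 are too few for a share below 0.05. For the genes between IKKb and IkB_SR the real split gave 142, the highest other of the 16 gave 5 and the highest other of the 100 gave 14, so 1 split of each set gave as many. The NF-kB list shift in this contrast was 1.03 (1 of 16, highest other 0.762; 1 of 100, highest other 1.01). Between IKKb and MiG it was 0.66 (1 of 16, highest other 0.559; 7 of 100, highest other 0.776), and between IkB_SR and MiG 0.38 in size (2 of 16, highest other 0.377; 13 of 100, highest other 0.673). Limma found 0 genes in each comparison with MiG, with 839 and 675 at an unadjusted p below 0.05, and since any count reaches 0, all 100 splits did and the count says nothing about chance (highest others 0 and 2). The numbers of lists past camera with a preset correlation were 12 for IKKb against MiG (1 of 16, highest other 11; 7 of 100, highest other 13), 7 for IkB_SR against MiG (6 of 16, highest other 9; 38 of 100, highest other 13) and 11 for IKKb against IkB_SR (7 of 16, highest other 14; 19 of 100, highest other 15).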

How the results depend on the processing

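The fits without the H358 IKKb array, the LLC block combined with other settings, the NF-kB list without NFKBIA and the overlap of 17 and 1 genes were chosen after the data were seen, and the other alternatives before. The 142 genes between IKKb and IkB_SR (93 higher, 49 lower) became 119 to 149 with other pseudocounts, quantile normalisation, median centring (106 higher, 31 lower), the 60th percentile filter and a robust prior. They became 86 with no filter, where more genes are tested, 45 with the mean of probe sets and 21 without a trend. They became 15 with the arrays of the compared vectors only and 24 to 129 without 1 line. With no cell line block limma found 0, with 87 at an unadjusted p below 0.05, where chance alone gives 761. Of the 31 named genes past the threshold there, those with a value (27 with the 60th percentile filter, 31 otherwise) kept their direction, and 8 to 31 stayed past it under settings with the block. Between IKKb and MiG the count was 1 (RAP1A, named after its value was seen) with the mean of probe sets and 0 in limma otherwise (44 to 1079 at an unadjusted p below 0.05). Between IkB_SR and MiG it was 1 (TNFAIP3) with the arrays of the compared vectors only, and 0 to 8 without 1 line. In LLC it was 2 (Mmp9 and Nfkbie) with a pseudocount of 64, 5 to 138 without 1 array, and 223 with the replicate block, which became 197 and 166 with pseudocounts of 1 and 64, 90 with quantile normalisation, 224 with median centring and 92 with no filter. The cause was not tested for the settings that keep genes and arrays.

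The NF-kB list kept its direction throughout, at 0.50 to 0.76, -0.47 to -0.32, 0.92 to 1.12 and 1.03 to 1.47 without 1 line or array. Without NFKBIA it lay at 0.64, -0.49 and 1.13 in the human comparisons. With an estimated correlation its shift of -0.38 with IkB_SR had an adjusted p of 0.115 and that of 1.25 in LLC one of 0.487. Ribosomal proteins turned between IKKb and MiG without the H358 IKKb array (-0.037) and over leave-outs of 1 line ran from -0.03 to 0.19. Between IKKb and IkB_SR they turned to -0.11 without that array and ran from -0.12 to 0.094, and cell cycle genes from -0.076 to 0.098. In LLC without 1 array, MHC class I genes ran from -0.094 to 0.43 and stress response genes from -0.54 to 0.27. The cause was not tested. With controls split, the correlation of the responses was -0.115 and the covariance -0.00993. Over all lists, 235 of 295 settings for IKKb against MiG, 245 of 295, 242 of 295 and 302 of 378 in LLC gave the same direction and side of the threshold. Signal near background limits the dim genes. LLC without a block found 44 of 100 simulated changes of log2 2, in arrays simulated with a difference between replicate numbers.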

Other observations

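The genes in this part were picked after their values were seen. C3, the central complement component, was 4.40-fold higher with IKKb than with IkB_SR (log2 2.14 ± 0.40, adjusted p = 0.0277) and CFB, a protease of the alternative complement pathway, higher by log2 1.76 ± 0.36 (adjusted p = 0.0351), each in 5 of 5 lines, from 0.63 in H23 to 4.70 in HCC827 for C3. The soluble pattern recognition gene PTX3 was higher by log2 2.93 ± 0.63 (adjusted p = 0.0429) in 4 of 5 lines, with A549 at -0.26. For CFB and PTX3, 2 of the 5 IkB_SR signals lay below the 40th percentile. Both NADP-dependent isocitrate dehydrogenases were lower, IDH1 by 1.48-fold (log2 -0.56 ± 0.12, adjusted p = 0.0422) and IDH2 by 1.66-fold (log2 -0.73 ± 0.12, adjusted p = 0.0101), each in 5 of 5 lines. Against MiG these 5 genes lay on opposite sides with IKKb and IkB_SR, without passing the threshold in either comparison (adjusted p = 0.878 with IKKb and 0.995 with IkB_SR). In LLC, Idh1 lay at -0.42 and Idh2 at -0.03 (adjusted p = 0.221 and 0.968 with the replicate block).

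Genes of salivary-type cystatins, inhibitors of cysteine proteases, stood out on the H358 IKKb array. CST1 had a signal of 15800 there, against 5.20 with MiG and 2.16 with IkB_SR in the same line, and CST4 had 15080 against 154.1 and 152.8. The CST2 probe set had 6689 against 30.7 and 31.3, and these related genes have similar sequences. In the other 4 lines the CST1 signal with IKKb and with MiG was 854 and 220 in A549, 30.03 and 5.633 in H23, both below the 40th percentile of their arrays, 70.85 and 44.16 in HCC827, and 226.3 and 76.55 in PC9. Over all 5 lines CST1 did not pass the threshold (adjusted p = 0.878).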
